A study of Mus musculus with 6 samples.

How the data were processed

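RNA was sequenced from sorted E7.5 mouse mesoderm of 2 genotypes, Mesp1-Cre with a tdTomato reporter at R26 (control) and Mesp1-Cre with Gli3R and Venus at R26 (Gli3R), in 3 libraries each. Per the labels' protocols, embryos were pooled with their littermates, dissociated with TrypLE for 5 minutes, stained with a dead-cell dye and sorted, with 1000 cells per library going straight into lysis buffer. The number of embryos per pool and the gates of the sort are not given in the sources used here. Per the labels' protocols, cDNA was made with the SMARTer Ultra Low RNA kit and libraries with Nextera XT. As general knowledge of these kits and not from the labels, neither keeps strand or tags single molecules, so amplified copies of a molecule count as separate reads.

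The authors deposited raw counts per gene, 1 value per library and Entrez gene ID. The submitters' processing notes name FastQC, TopHat2 2.0.14, Subread 1.4.6, featureCounts, edgeR and the genome build mm9, without saying what each was used for; the deposited counts carry the name of featureCounts. The gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here, so near-identical copies and overlapping or antisense genes are treated as uncertain. The reference at hand is of another build, so no chromosomal positions are given, and it was used only for names, chromosomes and transcript sequences. Of the Entrez gene IDs, 96.7% matched its gene table. The table held 27 symbols turned into dates, and all 27 were restored by their Entrez gene ID.

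Counts were analysed as deposited in R 4.3.3. Library totals ran from 5481190 to 12635151, so that 1 count stood for 0.0791 to 0.182 CPM and 3 counts, the limit that a count of 0 allows, for 0.237 to 0.547 CPM. These limits and all intervals on reads cover counting error only. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 11913 genes, and scaled by the trimmed mean of M-values (TMM). Gli3R was compared with control by the edgeR quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit held no other term. Log2 fold changes are given with standard errors and CPM values, TMM-scaled, with SDs over 3 libraries. The median log2 fold change of all tested genes lay within 0.01 of 0 under each scaling (-0.00787 with TMM, -0.00277 with DESeq2's size factors and 0.00348 with library size alone). Each library was compared with each other by chi-square per gene, which ran from 3.90 to 13.9, well above sampling noise. No library was therefore a copy or a random part of another's reads. This cannot show that the libraries came from separate pools of cells, since amplified copies count as reads. That each is a separate sample is taken from the labels.

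The labels give each library's litter, and a replicate number marks a shared litter. Deviations from the group means correlated at 0.168, 0.187 and 0.0755 within litters 1, 2 and 3 and at -0.269 to 0.162 between libraries of different litters, and 5 of 6 libraries correlated best with their own litter. Deviations sum to 0 within a group, so these matches are not independent, and litter 3 lay below the highest value between litters. They are weak evidence of a litter effect. The labels' pairing is followed in a second fit with litter as a block, which was chosen before the data were examined. Genes that the block gains or loses are named after the main counts. Blocked counts of list members adjusted over the list alone are given where they differ. The 3 litters are separate pools of animals, so p-values measure the spread between pools.

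Before the data were examined, 29 gene lists for pathways, cell types and sample states, and the rule for naming genes, were fixed. All 29 lists had the 5 tested members required. Named are Gli3; per direction up to 15 genes with the largest change among those that passed at a mean of at least 5 CPM and moved the same way in all 3 litters, or the 6 with the smallest p where fewer than 6 passed; Gli1, Ptch1, Hhip, Foxf1, Fgf4, Fgf8, T and Mesp1; and up to 4 tested members with the smallest p of each list. Of the genes so named, 2 list members are not reported here. List members beyond these are named where they passed adjusted over the list alone, and Tal2, Cpm and the genes gained with the litter block were added after their values were seen. Lists were tested with camera of limma 3.58.1 on log-CPM (prior count 2) with the preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 29 lists, and again with a correlation estimated from the residuals and with fry. A member counts as having risen or fallen at an adjusted p under 0.05, once over all genes tested and once adjusted over the list alone.

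The alternatives, chosen before the data were examined, were litter as a block; DESeq2's size factors or library size alone in the edgeR fit; no filter on low counts, or at least 5 CPM in 3 libraries; DESeq2 1.42.0, with and without litter; limma-voom; leaving out each library or each litter; a fold change of at least 1.5; and an adjusted p under 0.1. Counts of list members adjusted over the list alone were also made without each library, an alternative added after the data were seen. All 10 splits of the 6 libraries into 3 and 3 were run through the same fit.

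The edgeR fit was tested on 5 simulations drawn from these libraries' means, depths and dispersions, with 200 genes changed. A litter SD of 0.15 on the log2 scale was added, a value that was set and not estimated from these libraries. The dispersions came from a fit without litter, so they already held any litter spread. The shares that follow hold for this setting and may differ for the real libraries. A median of 11748 genes was tested. The fit without the block recovered 7.62% of genes changed 1.5-fold, 55.7% of those changed 2-fold and 93.1% of those changed 4-fold, and 4.54% of its calls were unchanged genes. With the block it recovered 27.7%, 65.1% and 94.4%, and 11.4% of its calls were unchanged genes. In the list test with the preset correlation, a list of 30 genes raised by 0.5 on the log2 scale was called and 0 of 20 unchanged lists were. The simulated genes varied independently of one another, so this cannot show how the list test behaves for lists whose genes vary together. Transcripts of named genes were aligned to all others with BLAST 2.17.0, and a match counted at 95% identity over 100 bases. Of 105 named genes with a transcript, 6 shared at least 50% of it with another gene, namely Gm14680, Gdf1, Hspd1, Ccnb1, Hoxb3 and Nrarp.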

Results

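The experiment asked which transcripts of the early mouse mesoderm depend on Hedgehog signalling. Gli3R, a repressor form of the Hedgehog transcription factor Gli3 that acts as a dominant negative of the pathway, was expressed from the R26 locus together with Venus in embryos carrying Mesp1-Cre, a recombinase driven by a gene of the nascent mesoderm. Control embryos carried Mesp1-Cre with a tdTomato reporter at R26. The reporter thus differed between the groups in every litter, and the gates of the sort are not given. An effect of Gli3R therefore cannot be told apart from an effect of the reporter or of how the cells were gated. Mesoderm cells were sorted at embryonic day 7.5, and 1000 cells per library were used for RNA sequencing. There were 3 control and 3 Gli3R libraries, with 1 library of each group from each of 3 litters and the embryos of a library pooled with their littermates. Control replicates 1, 2 and 3 held 5481190, 10435790 and 7859087 counts, and Gli3R replicates 1, 2 and 3 held 12635151, 7820726 and 6592417. Of 24975 genes in the table, 6256 had no count in any library and 11913 were expressed enough to be tested. The first principal component, with 35.0% of the variance, set control replicate 1, the shallowest library, apart at -39.9, while the other libraries lay between -2.25 and 19.3.

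Gli3 itself was read first, since the transgene carries part of it. Its level averaged 29.9 ± 4.30 CPM (counts scaled to library size; SD, n = 3) in the control libraries and 44.5 ± 6.04 CPM in the Gli3R libraries. Each Gli3R library (39.0 to 50.9 CPM) lay above each control library (25.8 to 34.4 CPM). Groups that do not overlap, in either direction, were seen in 12% of all tested genes, near the 10% that chance gives. The separation is therefore weak evidence. The log2 fold change of 0.57 ± 0.15 (SE) did not pass over all genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.312). Counts per gene do not separate transcripts of the transgene from those of the endogenous Gli3 gene.

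The genes that fell with Gli3R included ligands and regulators of FGF, Notch and activin signalling. The FGF ligand Fgf3 (Entrez gene 14174) fell from 41.8 ± 9.78 to 10.5 ± 1.00 CPM, and the FGF ligand Fgf15 (14170) from 118 ± 19.6 to 45.5 ± 10.7 CPM (SD, n = 3 each). Fst (14313), which encodes the secreted activin antagonist follistatin, fell from 49.4 ± 7.01 to 15.4 ± 2.20 CPM, and the Notch ligand gene Dll3 (13389) from 14.03 ± 2.71 to 4.34 ± 0.28 CPM. Ccnd1 (12443), the cyclin D1 gene, fell from 90.6 ± 2.54 to 48.8 ± 7.03 CPM. Ahnak (66395) rose from 42.6 ± 4.83 to 85.5 ± 7.77 CPM, and Emp2 (13731), an epithelial membrane protein gene, rose from 7.068 ± 1.154 to 16.6 ± 1.49 CPM.

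In all, 3 genes were higher and 13 lower with Gli3R at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Each of the 16 moved the same way in all 3 litters, as did 30.3% of all tested genes. Selection by p in the same libraries favours such genes, so this is no separate support. The log2 fold changes (± SE) of the genes above were -1.98 ± 0.19 for Fgf3, -1.37 ± 0.17 for Fgf15, -1.68 ± 0.16 for Fst, -1.67 ± 0.21 for Dll3, -0.89 ± 0.12 for Ccnd1, 1.00 ± 0.12 for Ahnak and 1.21 ± 0.18 for Emp2. Their adjusted p-values in the edgeR quasi-likelihood test ran from 0.00450 for Fgf3 and Fst to 0.0461 for Emp2. The other genes that fell included Gal, which encodes the neuropeptide galanin (-3.63 ± 0.43), Hsd11b2, a steroid dehydrogenase gene (-1.93 ± 0.27), the parathyroid hormone receptor gene Pth1r (-1.26 ± 0.14), Arl4a (-1.11 ± 0.16) and Cfc1, a Nodal co-receptor gene (-0.80 ± 0.11). The spermine synthase gene Sms (-1.09 ± 0.10) and its near-identical copy Gm14680 (-1.14 ± 0.10) also fell, and reads of the part they share cannot be assigned to either with certainty. Tal2, a basic helix-loop-helix factor gene (2.39 ± 0.34), and Cpm, the carboxypeptidase M gene (-2.37 ± 0.34), passed at a mean of 2.46 and 3.03 CPM; they fell below the expression set for naming and were added after their values were seen. Of genes higher with Gli3R, Tal1 (0.96 ± 0.15), a blood and endothelial transcription factor gene, missed the threshold at an adjusted p of 0.0506 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and Rnd2, F2r and Msx1os, which overlaps Msx1, missed it as well.

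With litter as a block, 9 genes were higher and 18 lower, and 13 of the 16 were called again, all in the same direction. Cfc1 and Tal2 (adjusted p = 0.0502 each) and Cpm (0.0555) missed the threshold of the edgeR quasi-likelihood test there. Those gained were Lgals9, Msx1, Msx1os, Csrp1, Bmp4, Cdkn1c and Ndrg1 among the higher genes and Cdh1, Pdlim4, Fabp7, Cited1, Bcat1, T and Cdx1 among the lower ones. List members passing over all genes tested are counted below without the block. The block adds Bmp4 to the Hedgehog, lateral plate and extraembryonic lists and Msx1 to the lateral plate, extraembryonic and BMP lists. It adds Cdh1 to the epiblast and epithelial-mesenchymal lists and T and Cdx1 to the streak and WNT lists. T also joins the node and FGF and ERK lists, and Ndrg1 the hypoxia list. The count of 16 moved with single libraries: 0 genes passed without Gli3R replicate 3 (659 at an unadjusted p under 0.05) and 5 to 9 without control replicate 2, control replicate 3, Gli3R replicate 1 or Gli3R replicate 2.

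**Figure D1:**
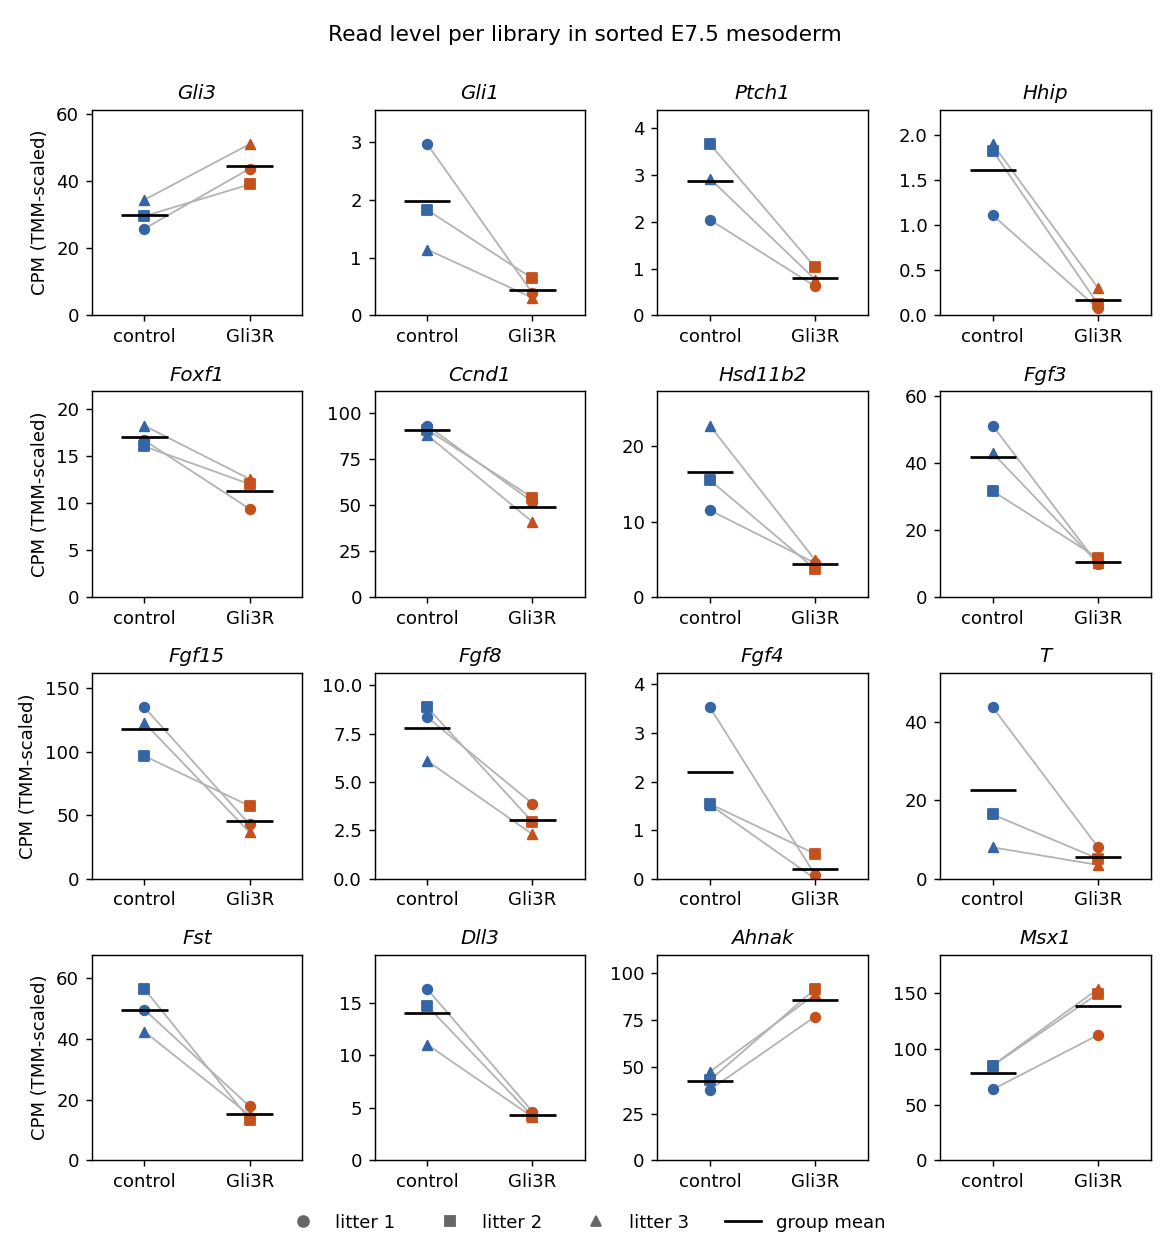
Read level in CPM on the vertical axes of 16 genes in each library, control in blue and Gli3R in orange, with lines joining the libraries of a litter (circle, square and triangle for litters 1, 2 and 3) and black bars at the group means. Fgf3, Fst and Dll3 lay lower and Ahnak higher with Gli3R in all 3 litters, while T ranged from 7.99 to 43.6 CPM among the control libraries.

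Transcripts that serve as direct readouts of Hedgehog signalling were sparse in these libraries, with fewer reads in the Gli3R group. Ptch1, which encodes the Hedgehog receptor, had 72 reads in the control and 21 in the Gli3R libraries, or 2.87 ± 0.81 against 0.80 ± 0.20 CPM (SD, n = 3). Its log2 fold change of -1.89 ± 0.38 (SE) did not pass over all genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.169). Gli1, a transcription factor gene induced by the pathway, had 44 against 12 reads and was 4.21-fold lower, with a 95% interval of 2.19 to 8.76 that covers counting error only. Hhip, which encodes a Hedgehog-binding protein, had 40 against 4 reads and was 11.5-fold lower (4.15 to 44.2). Both were under the expression filter. When it was dropped, Hhip fell and Gli1 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0234 and 0.139 over 18719 genes).

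Of 21 Hedgehog target genes tested, 2 fell over all genes tested (Ccnd1 and Hsd11b2) and 0 rose; adjusted over the list alone, 9 fell and 4 rose. Those that fell adjusted over the list alone included Ptch1, the forkhead genes Foxf1 (log2 fold change -0.60 ± 0.17), Foxf2 (-1.39 ± 0.32) and Foxc2 (-0.76 ± 0.29), Osr1 (-1.37 ± 0.34) and Mycn (-0.49 ± 0.14). Those that rose were Bmp4 (0.68 ± 0.16), Cdon (0.83 ± 0.28), Snai2 (0.69 ± 0.26) and Cyp26a1 (0.32 ± 0.12). The list was not split into genes that the pathway induces and genes that it represses. A rise of a member is therefore not in itself a sign of higher pathway output. Without control replicate 1 or 2 or Gli3R replicate 2 or 3, 1 or 2 rose, and with the litter block 5 rose and 11 fell. The list as a whole was lower (camera, preset correlation, Benjamini-Hochberg adjusted p = 3.84e-04 over 29 lists), with adjusted p = 0.257 with an estimated correlation. Of 14 Hedgehog pathway components, 0 changed over all genes tested; adjusted over the list alone, Ptch1 fell and Gli3 rose, and the list did not pass (camera adjusted p = 0.935).

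Among 10 FGF ligands and receptors, Fgf3 and Fgf15 fell over all genes tested; adjusted over the list alone, Fgf4 and Fgf8 fell too and the receptor gene Fgfr3 rose (0.85 ± 0.25), while 0 rose without Gli3R replicate 3. Fgf8 stood at 7.76 ± 1.47 CPM in control and 3.04 ± 0.80 CPM in Gli3R libraries, and Fgf4 had 47 against 5 reads. The list did not pass as a whole (camera adjusted p = 0.185), but it was lower in 4 of 6 fits without a library (control replicate 2 and Gli3R replicates 1, 2 and 3, at 0.0179, 0.0461, 0.00254 and 0.0113) and without the low-count filter (0.0380). Of 21 FGF and ERK feedback and target genes, 0 passed over all genes tested; adjusted over the list alone, Phlda1 rose (0.95 ± 0.20), and the feedback inhibitor gene Spry1 stood at -0.57 ± 0.19 (camera adjusted p = 0.397). With litter as a block, 2 members of that list rose and 2 fell, adjusted over the list alone.

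Genes of the paraxial and presomitic mesoderm, which forms the somites, gave the lowest camera p of the 29 lists. Of 19 tested members, Fst and Dll3 fell over all genes tested; adjusted over the list alone, 12 fell and Pax3 rose (1.10 ± 0.39). Among the 12 were the segmentation gene Ripply2, at 7.73 ± 0.91 CPM in control and 0.73 ± 0.71 CPM in Gli3R libraries, the Notch ligand gene Dll1 (-2.18 ± 0.50), the presomitic transcription factor gene Msgn1 (-1.91 ± 0.60) and Aldh1a2, which makes retinoic acid (-1.19 ± 0.30). Between 8 and 15 members fell when a library was left out, and 1 rose without control replicate 2 against 0 without any other library; with the litter block 15 fell and 1 rose. The list of Notch target genes overlaps the paraxial list, and it also holds Notch receptor genes and ligand genes such as Dll1 and Dll3. Of 11 tested, Dll3 fell over all genes tested, and adjusted over the list alone Dll1 and Hey1 (-0.90 ± 0.26) fell as well. The paraxial list and the Notch list were lower (camera, preset correlation, Benjamini-Hochberg adjusted p = 3.29e-12 and 1.43e-03), each with adjusted p = 0.257 with an estimated correlation.

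Primitive streak and nascent mesoderm genes were lower as a list by camera with the preset correlation (Benjamini-Hochberg adjusted p = 3.07e-08) and did not pass with an estimated correlation (0.521). Of 25 tested, 0 passed over all genes tested. Adjusted over the list alone, Fgf4, Fgf8, Pou5f1, T, Grsf1 and Mesp2 fell and 0 rose. T, the Brachyury gene of the streak, stood at 43.6, 16.4 and 7.99 CPM in control replicates 1, 2 and 3 and at 8.08, 5.13 and 3.53 CPM in the Gli3R replicates of the same litters. It did not pass without the litter block and fell with it (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.402 and 0.0373). With the block, 16 streak genes fell and 1 rose adjusted over the list alone; without it, leaving out a library gave between 2 (Gli3R replicate 3) and 16 (Gli3R replicate 1) that fell. Mesp1, whose Cre marks these cells, stood at -0.51 ± 0.35 and at 0.05 without litter 1.

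Markers of epiblast and neural ectoderm were lower as a list by camera with the preset correlation (Benjamini-Hochberg adjusted p = 1.62e-04) and did not pass with an estimated correlation (0.521). Of 14 tested, 0 changed over all genes tested, and 7 fell adjusted over the list alone, among them the E-cadherin gene Cdh1 (4.36 ± 2.57 against 0.45 ± 0.13 CPM), Hesx1 (-2.71 ± 0.55), Epcam (-1.12 ± 0.29) and Pou5f1 (-1.10 ± 0.30). Between 3 (without Gli3R replicate 3) and 10 (without control replicate 3) fell when a library was left out, with 4 without control replicate 1 or 2, and 7 fell and 1 rose with the litter block. Of 20 canonical WNT target genes, Ccnd1 fell over all genes tested; adjusted over the list alone, Tnfrsf19 (-0.53 ± 0.13) and T fell too, and 9 fell with the litter block. Leaving out a library gave between 1 (control replicate 1) and 9 (Gli3R replicate 1) WNT targets that fell. The WNT list was lower (camera, preset correlation, Benjamini-Hochberg adjusted p = 9.01e-04), with adjusted p = 0.521 with an estimated correlation. Without control replicate 1, the WNT list did not pass (camera adjusted p = 0.0782).

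Genes of the extraembryonic mesoderm and allantois were higher as a list by camera with the preset correlation (Benjamini-Hochberg adjusted p = 5.80e-04) and did not pass with an estimated correlation (0.713). Of 29 tested, Ahnak rose and Hsd11b2 fell over all genes tested; adjusted over the list alone, 8 rose and 1 fell. Among the 8 were the homeobox gene Msx1 (77.9 ± 12.4 against 138 ± 22.7 CPM), Bmp4 (126 ± 25.2 against 203 ± 35.7 CPM), the smooth muscle gene Tagln (0.92 ± 0.24) and Peg3 (0.40 ± 0.08). With the litter block, 17 rose and 3 fell adjusted over the list alone; leaving out control replicate 3 gave 16 that rose, and leaving out control replicate 2 or Gli3R replicate 2 or 3 gave 3 or 4, while 6 fell without control replicate 1. Endothelial genes went both ways: of 24 tested, 0 changed over all genes tested, and adjusted over the list alone Tal1, Hhex (0.88 ± 0.16), Etv2 (0.62 ± 0.15), Nrp1 and Fli1 rose while Lmo2 (-0.92 ± 0.18) and Aplnr (-0.66 ± 0.14) fell, with 3 that rose without control replicate 2 or Gli3R replicate 2. The endothelial list was higher (camera, preset correlation, Benjamini-Hochberg adjusted p = 0.0150), with adjusted p = 0.563 with an estimated correlation. Neither list passed without control replicate 1 (camera adjusted p = 0.687 and 0.585), nor the endothelial list without Gli3R replicate 2 (0.0550) or without the low-count filter (0.108).

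The p-values of camera with the preset correlation were weak evidence in these libraries, since other splits of the same 6 libraries called up to 14 lists against 8 for the real one. The splits that called more than 8 put both libraries of a litter on 1 side. The other splits that part every litter called 6, 0 and 1 lists. Under the estimated correlation 0 lists passed, with or without the litter block. That variant had little power with 6 libraries, so this does not show that the lists were unchanged. Its lowest unadjusted camera p was 0.0125, for the paraxial list. The Notch list, with an estimated correlation of -0.095, went from an unadjusted camera p of 3.45e-04 (preset) to 0.0199. The simulations did not cover this variant. The rotation test fry, which asks whether a list's genes move 1 way on balance, called the Notch, paraxial and Hedgehog target lists lower (Benjamini-Hochberg adjusted p = 4.45e-04, 0.0309 and 0.0309) and 0 lists with the litter block. Another split also gave more members that passed, adjusted over the list alone, than the real one for the streak, extraembryonic, erythroid, endoderm, node, FGF and ERK target, epithelial-mesenchymal and retinoic acid lists, so member calls in these are weak evidence too.

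**Figure D2:**
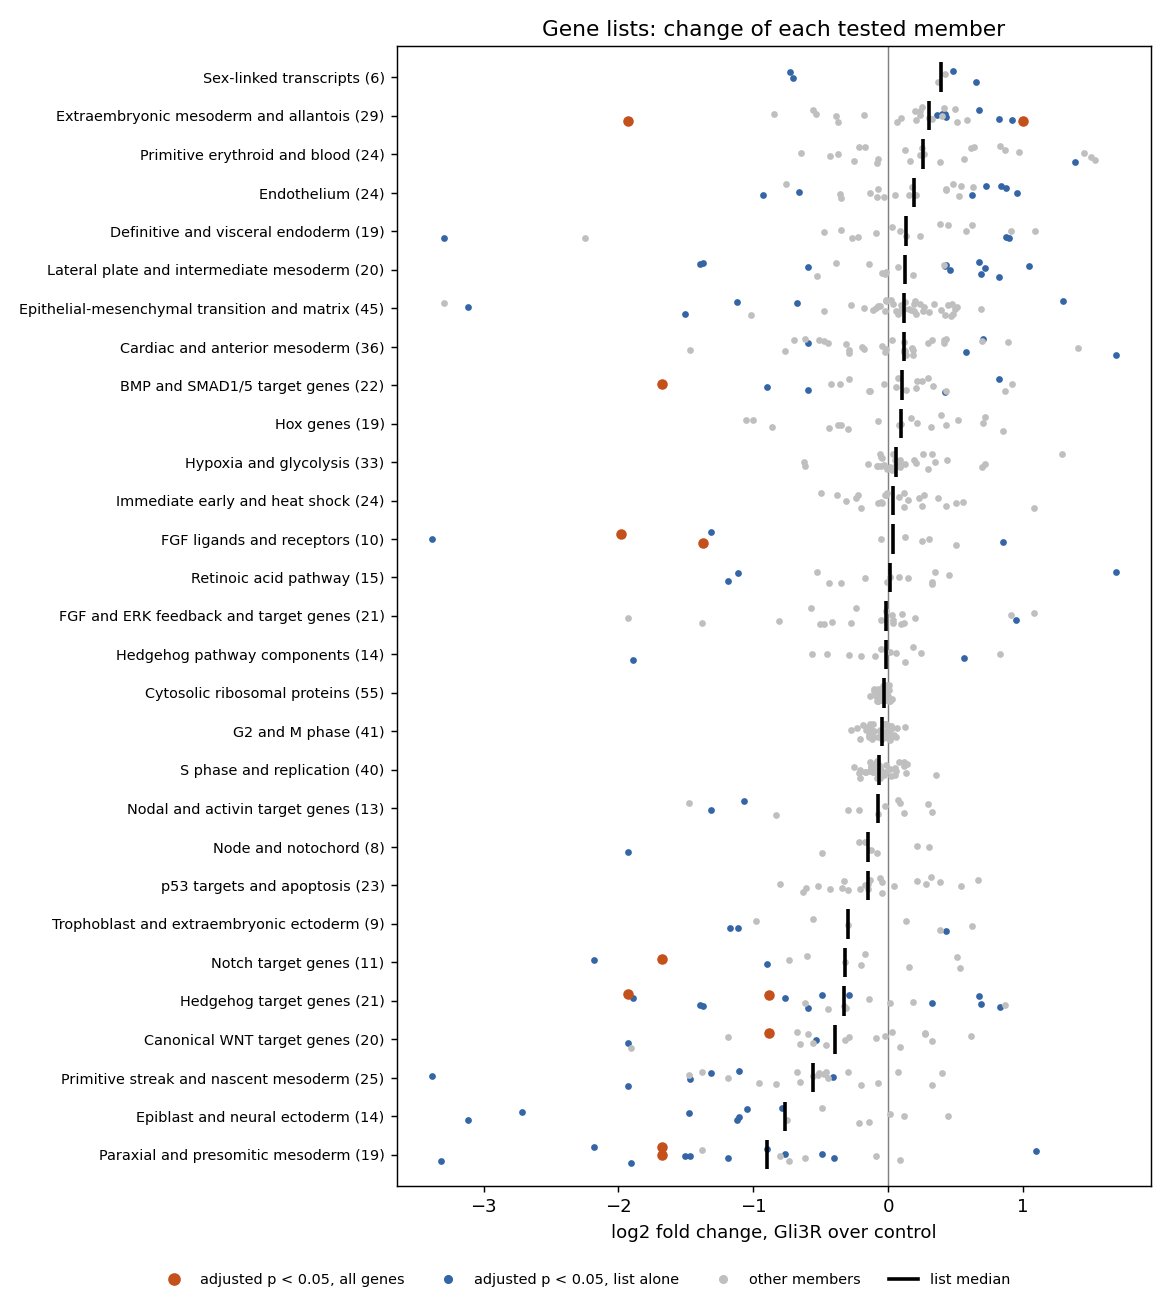
Log2 fold change of Gli3R over control for each tested member of 29 gene lists (number tested in parentheses), with a black bar at the list median, orange points for members that passed over all genes tested and blue points for members that passed adjusted over the list alone. The paraxial list has the lowest median (-0.90) and the 55 ribosomal protein genes lie close to 0.

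Lateral plate and intermediate mesoderm genes changed in both directions. Of 20 tested, 0 passed over all genes tested; adjusted over the list alone, 8 rose, among them Msx1, Bmp4, Prrx1 (1.05 ± 0.28) and Hoxb6 (0.72 ± 0.23), and Foxf1, Foxf2 and Osr1 fell (camera adjusted p = 0.269). Without control replicate 1 or 2 or Gli3R replicate 3, 3 or 4 rose, and with the litter block 7 rose and 3 fell. BMP and SMAD1/5 target genes were likewise split: of 22 tested, Fst fell over all genes tested, and adjusted over the list alone Msx1 and Msx2 rose while Fst, Foxf1 and Hey1 fell (camera adjusted p = 0.677), with 3 and 3 under the litter block. Of 36 cardiac and anterior mesoderm genes, 0 passed over all genes tested; adjusted over the list alone, the cardiac actin gene Actc1 (0.71 ± 0.18), Cyp26c1 and Meis1 rose and Foxf1 fell (camera adjusted p = 0.289), and with the litter block 7 rose and 3 fell. The cardiac list was higher without control replicate 3 (camera adjusted p = 0.0245).

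The other signalling lists had 0 members that passed over all genes tested. Adjusted over the list alone, Gdf1 (-1.07 ± 0.17) and Fgf8 fell among 13 Nodal and activin target genes (camera adjusted p = 0.185), with 1 that rose and 4 that fell under the litter block. That list was lower without control replicate 3, Gli3R replicate 3 or the low-count filter (0.0245, 0.0265 and 0.00302). The Gdf1 transcript is contained in that of Cers1, and its reads cannot be assigned to either with certainty. Among 15 retinoic acid pathway genes, Cyp26c1 rose (1.69 ± 0.44) and Aldh1a2 and Stra6 fell adjusted over the list alone (camera adjusted p = 0.935), with 3 and 4 under the block. Cyp26c1 was sparse, with 11 reads in the control and 41 in the Gli3R libraries. Of 45 genes of the epithelial-mesenchymal transition and matrix, Col1a1 rose (1.30 ± 0.31) and Cdh1, Vcan, Epcam and Pcdh8 fell adjusted over the list alone (camera adjusted p = 0.192, and 0.00516 upward without control replicate 3), with 5 and 5 under the block. Of 19 Hox genes, 0 passed adjusted over the list alone (camera adjusted p = 0.273), while Hoxb2 (0.39 ± 0.11) and Hoxb6 (0.72 ± 0.23) rose and Hoxa2 fell under the block. Hoxa2 stood at 7.52 ± 1.13 CPM in control and 3.65 ± 1.37 CPM in Gli3R libraries (SD, n = 3) and was lower in all 3 litters.

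Apart from the epiblast and endothelial lists given above, markers of other cell types and of sample state did not pass as lists. Without the litter block, 0 of their members passed over all genes tested. Adjusted over the list alone, Myb rose (1.38 ± 0.33) among 24 primitive erythroid and blood genes (camera adjusted p = 0.185), and 4 rose under the litter block. The erythroid list was higher without control replicate 1 or Gli3R replicate 3 (0.00614 and 0.00642). Among 19 endoderm genes, Hhex and Krt19 rose and Cldn6 fell (-3.29 ± 0.96; camera adjusted p = 0.289, and 0.0405 upward without control replicate 2), with 6 and 2 under the block. Among 9 trophoblast genes, Hand1 rose and Sct and Ascl2 fell (camera adjusted p = 0.273), with 1 and 1 under the block. T fell among 8 node and notochord genes (camera adjusted p = 0.202, and 0.00302 downward without the low-count filter), and 1 rose and 1 fell under the block. Among 6 sex-linked transcripts, the Y-linked Ddx3y (0.66 ± 0.16) and Eif2s3y (0.48 ± 0.12) rose and Xist (-0.70 ± 0.13) and its antisense partner Tsix fell, all adjusted over the list alone (camera adjusted p = 0.403), and 3 rose and 2 fell under the block. The strand setting of the counting is not given in the sources used here, so reads of the part that Xist and Tsix share cannot be assigned to either with certainty.

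Proliferation and housekeeping genes had 0 members that passed without the litter block. Members that passed, adjusted over the list alone, numbered 0 of 41 for G2 and M phase (camera adjusted p = 0.0972), 0 of 40 for S phase and replication (0.149), 0 of 23 for p53 targets and apoptosis (0.266), 0 of 24 for immediate early and heat shock genes (0.935), 0 of 33 for hypoxia and glycolysis (0.185) and 0 of 55 for cytosolic ribosomal proteins (0.289). Leaving out a library brought some lists past the threshold of camera: G2 and M phase was lower without control replicate 1 or Gli3R replicate 2 (0.00220 and 0.00701) and S phase without control replicate 3 or Gli3R replicate 1 (0.0418 and 0.0461). Ribosomal proteins were lower without control replicate 3 or Gli3R replicate 3 (0.0390 and 0.0354). Hypoxia and glycolysis was higher without control replicate 3 or Gli3R replicate 1 (0.0390 and 0.00255), and immediate early genes without Gli3R replicate 1 (0.0257). Under the litter block, 3 hypoxia and glycolysis genes rose, Ndrg1 among them, and 1 fell. The replication gene Mcm2 stood at -0.20 ± 0.08 and the mitotic kinase gene Aurka at -0.19 ± 0.08. The median and mean log2 fold change had opposite signs for FGF ligands and receptors (0.04 and -0.61, with the test downward), the epithelial-mesenchymal list (0.12 and -0.07, upward), endoderm (0.13 and -0.03, upward) and retinoic acid (0.01 and -0.03, upward).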

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

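The counts of member genes adjusted over the list alone without single libraries were chosen after the data were seen; the other alternatives were planned. Of 102 named genes tested, 14 were called and 0 of these changed direction in any alternative. Genes higher and lower (3 and 13 as reported) numbered 7 and 23 at an adjusted p under 0.10, 9 and 18 with the replicate block, 5 and 14 with library size alone, 49 and 59 without the low-count filter (18719 genes tested), 1 and 12 at 5 CPM or more, 43 and 51 with DESeq2 (adjusted p NA for 3 genes), 38 and 40 with DESeq2 and the replicate block (NA for 462), and 1 and 9 with limma-voom; DESeq2's size factors and a 1.5-fold minimum gave 3 and 13 again. The cause of these shifts was not tested. DESeq2, with or without the block, and the fit without the filter called all 16 genes again, and limma-voom called 10.

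Without a library or a litter, genes higher ran from 0 to 123 and lower from 0 to 98, the highest both without litter 1 under the replicate block. Counts of 0 came without Gli3R replicate 3 and without litter 3 (659 and 747 at an unadjusted p under 0.05 in the edgeR fit; 1079 with the block), and 0 higher genes also came without control replicate 2 or Gli3R replicate 2 and without litter 2. Fewer libraries enter these fits. Mesp1 ran from -1.02 to 0.088 on the log2 scale and Rpl17 from -0.14 to 0.030, above 0 without litter 1 and, for Rpl17, without control replicate 1.

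Of 29 lists, 8 passed as reported, and the same 8 with the replicate block and with DESeq2's size factors; 10 passed without the filter (FGF ligands, Nodal targets and node gained, endothelium lost), 3 with fry, and 0 with an estimated correlation, with or without the block. Leaving out a library gave 7 (control replicate 1) to 14 (control replicate 3). Lists far from the threshold changed sign: Hedgehog pathway components and retinoic acid with the block (adjusted p = 0.905 and 0.988) and with the block and an estimated correlation (0.913 and 0.995), BMP targets with fry (0.917), and FGF and ERK targets and Hox genes without the filter (0.765 and 0.945). Over left-out libraries, camera's adjusted p ran from 0.442 to 0.976 for Hedgehog components, 0.0245 to 0.779 for cardiac, 0.00614 to 0.927 for erythroid, 0.0405 to 0.976 for endoderm, 0.123 to 0.971 for BMP targets, 0.104 to 0.665 for Hox, 0.227 to 0.971 for retinoic acid, 0.0257 to 0.755 for immediate early and 0.0354 to 0.927 for ribosomal genes, each list changing sign in at least 1 of these fits. The cause was not tested. The calls that the block changes are given in the report. Depth limits Gli1, Hhip, Fgf4 and Cyp26c1, with at most 56 reads in all.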

Other observations

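The tests on epiblast cells in the control sort, on the Hox genes as a sign of stage and on the streak and epiblast lists without control replicate 1, and the counts of members by library, were chosen after the results were seen; the other tests were set before theirs.

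Genes called with the litter block but not without it add to both directions. Lgals9, the galectin-9 gene, rose from 1.19 ± 0.58 to 8.43 ± 4.14 CPM (SD, n = 3), the cell cycle inhibitor gene Cdkn1c from 57.6 ± 15.2 to 104 ± 29.5 CPM and Csrp1 from 74.9 ± 14.9 to 134 ± 29.5 CPM. Cited1 fell from 62.2 ± 20.1 to 28.1 ± 6.25 CPM, the fatty acid binding protein gene Fabp7 from 12.9 ± 4.60 to 3.24 ± 1.65 CPM and the caudal-type homeobox gene Cdx1 from 27.97 ± 16.8 to 11.4 ± 10.1 CPM. Their blocked adjusted p-values in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment were 0.0121, 0.0238, 0.0191, 0.0144, 0.0191 and 0.0327. Without the block the same test gave 0.0506, 0.338, 0.189, 0.171, 0.169 and 0.740. In the simulations 11.4% of blocked calls were unchanged genes, against 4.54% without the block. Each of these 6 genes moved the same way in all 3 litters, which selection by the blocked fit favours. For Cdx1, Gli3R replicate 1 (23.1 CPM) lay above control replicates 2 and 3 (19.7 and 16.9 CPM).

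In the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave as many as 16 changed genes, and the highest of the others gave 0. With the litter block the real split gave 27 and the highest of the other splits that part every litter gave 0. For lists, 4 of 10 splits gave 8 or more, and the highest other gave 14. Among the splits that part every litter, the real one gave 8 lists and the others 6, 0 and 1. With 10 splits no share under 0.1 can be reached. Counts of members adjusted over the list alone, real against the highest other split, were 13 against 2 for the paraxial list, 13 against 1 for Hedgehog targets, 11 against 3 for lateral plate, 7 against 0 for endothelium and 5 against 0 for FGF ligands and receptors, but 6 against 9 for the streak and 9 against 14 for the extraembryonic list. Another split also gave more for erythroid (1 against 11), FGF and ERK targets (1 against 5), the epithelial-mesenchymal list (5 against 9), endoderm (3 against 5), retinoic acid (3 against 4) and node (1 against 2), and as many for Nodal targets (2 against 2). Lists with 0 in the real split reached 5 for hypoxia and 2 each for Hox, G2 and M phase and immediate early genes. Splits that call more members than the real one point to a structure of the libraries other than genotype in the genes of these lists. Member counts were not made separately for the splits that part every litter, so whether this structure is litter was not tested.

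The paraxial, streak and epiblast lists were each lower by camera with the preset correlation, and none passed with an estimated correlation (adjusted p = 0.257, 0.521 and 0.521). Control replicate 1 stood apart from the other libraries. That library alone as the cause is argued against for the paraxial genes. Without it, 18 of 19 members stayed below 0, with a median of -0.64 against -0.90 with it, and 8 fell adjusted over the list alone. Camera with the preset correlation, weak evidence here, gave an adjusted p of 5.25e-09 downward (0.391 with an estimated correlation). In 12 of 19 members, controls 2 and 3 both lay above every Gli3R library. These genes may vary together, and that share was not counted over all tested genes. For the streak and epiblast genes, control replicate 1 alone as the cause stays open for the lists as a whole. Without that library camera gave 5.65e-04 and 0.00778 downward (0.605 and 0.762 with an estimated correlation) and 4 members of each list fell, but the medians shrank from -0.56 to -0.37 and from -0.77 to -0.30. Controls 2 and 3 lay above every Gli3R library in 6 of 25 and 6 of 14 members. Epiblast cells carried into the control sort stay open. The 17 paraxial members outside the epiblast and streak lists had a median log2 fold change of -0.80, but no value here shows that such cells lack these transcripts. Of 10 epiblast members under 20 CPM in the controls, 1 was above 0, and the sort for the Mesp1 lineage would remove such cells only as far as its gates hold. A slightly later stage of the Gli3R embryos, with fewer streak cells, may also play a part and cannot be told apart from an effect of Gli3R on these cells, since the Hox genes had a median of 0.10 that decides neither way.

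Y-linked genes were higher and Xist lower with Gli3R in 14 of 15 pairs of gene and litter (11 of 12 for Ddx3y, Eif2s3y, Kdm5d and Uty, and 3 of 3 for Xist), which is consistent with pools holding more male embryos in the Gli3R groups. All these genes read the sex mix of the same 3 pairs of pools, so the 15 pairs are not independent. The test could have come out the other way, but the sex of the embryos is not given in the sources used here. Of the 16 called genes, 2 (Sms and Gm14680) are annotated on the X or Y chromosome, so most calls are of genes not annotated there. Among 11913 genes tested, 447 are annotated on the X. This count cannot show whether a different sex mix moved autosomal genes, so its part in the 16 calls stays open.

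Sms and Gm14680 fell by the same amount with little spread, Sms from 131 ± 3.06 to 61.3 ± 6.72 CPM. Reads shared between them may make the calls a single signal, since 100% of the Gm14680 transcript aligns to Sms. A shift of the whole X chromosome is argued against, since 447 tested X-linked genes had a median of -0.00815. An effect of Gli3R on Sms, or a sequence variant at this locus that differs between the groups, stays open and was not tested.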
